A study of Rattus norvegicus with 2 samples.

How the data were processed

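Gene expression was measured in 2 samples of rat heart on 2-colour Agilent oligonucleotide microarrays. On each array, heart RNA labelled with Cy3 was hybridised together with RNA labelled with Cy5 from a common pool, here called mix1 as in the labels. Mix1 combined cultured rat bone marrow cells with cultured rat primary ear fibroblasts, whereas the heart material was not cultured, per the labels. RNA was extracted with TRIzol and cleaned on a column, per the labels' protocols. The labels number the heart samples 1 and 2 and do not say whether they came from separate animals, so that the p-values measure only the spread between these 2 samples, which may be technical. Mix1 served as the control RNA and was not hybridised as a sample of its own. It therefore counted as 1 control sample, and each test of the ratio against 0 leaves out the spread of the control. There was no dye swap, so any dye bias of a probe points the same way on both arrays and stays in its ratio.

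The deposited table held 1 value for each of 40012 probes on each array, with no missing value and no value of exactly 0. Per the submitters' processing notes, Agilent Feature Extraction was used. Its version, the background correction and the dye normalization are not given in the sources used here. The deposited values were taken as log2 ratios of the 2 channels. The base was inferred from the values: the largest ratio was 2191-fold when read as log2, while a value of -11.10 read as log10 would lie far beyond what a 16-bit scanner can resolve. The design had assumed base 10 unless the values contradicted it. Read as natural logs, that value would be 65989-fold, just beyond the same range, while the largest on array 2 would be 62570-fold and within it. This margin is too narrow to decide on processed signals, and natural logs were tried as an alternative. The direction of the deposited ratio was likewise unstated. The series text speaks of heart relative to mix1, and the cardiac sarcomere list was fixed in advance as the check of orientation. All 24 of its measured genes were positive on both arrays, with medians of 5.65 and 5.75. Positive values were therefore read as higher in heart, which makes the ratio Cy3 over Cy5, the opposite of Agilent's usual red over green. This direction is likely and not stated, and the direction of the sarcomere list is no finding. The array medians were 0.01 and -0.14, so the columns had not been centred on their medians. No spot intensity was used here. The signal over background behind a ratio is therefore unknown, and a ratio in which 1 channel lay near background depends on how the authors treated that background. The number of arrays limits the precision.

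The platform's annotation gave a single gene symbol for 20417 probes, several symbols for 0 and none for 19595, which are unnamed here. Accessions without versions were matched to the GRCr8 gene table for 16978 probes, and this updated the symbol of 2251. A probe without a match took the current symbol of matched probes with the same annotated symbol, where these gave a single one. The remaining probes kept the symbol of the annotation. The probes of a gene were averaged on the log2 scale, which gave 15613 genes, 11845 of them with 1 probe. Of the 3768 genes with 2 or more probes, 44 had probes at least 2-fold higher and others at least 2-fold lower in heart. No coordinates are given because no genome build is named for the table.

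Probes and genes were tested with limma 3.58.1 in R 4.3.3. An intercept was fitted with lmFit and moderated with eBayes, which left 1 residual degree of freedom before moderation. The tests were two-sided, and p-values were adjusted with the Benjamini-Hochberg method at a threshold of 0.05. The prior degrees of freedom were 1.28 for probes and 1.24 for genes. Gene lists fixed before the data were examined, 32 in all, were tested with limma's camera at a preset correlation between genes of 0.01, and each list had at least 5 measured genes. Camera was also run with an estimated correlation, and the median of each list was set against 10000 random lists of the same size, which could not be matched on expression level because no intensities were used. The code was tested on simulated data drawn from the fitted variances. With 11385 of 15613 genes changed, as many as were called, 89.6% of the changed genes were recovered. Among the remaining, unchanged genes, 122 were called. The simulated unchanged genes held no dye bias and no spread of the control, so this count does not bound false calls in the measured data. With as many probes changed as were called, 87.9% of 26056 were recovered. With 200 genes changed among 15613, 70% of those with a log2 change of 2 and 0% of those with a change of 1 were recovered. With 200 probes changed among 40012, 0% were recovered at any size up to 4. The power of the test thus rests on how many features differ.

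Named genes were chosen by a rule fixed in advance. It took the 10 characterised genes with the largest mean log2 ratio in each direction, among those past the test with the same sign on both arrays. From each list it took up to 2 members higher and up to 2 lower, and the member not past the test with the largest mean. The surfactant and other genes that differed most between the arrays were named after their values were seen. A list of further lung genes was drawn up after the surfactant values were seen but before its own values were. The alternatives comprised centring or scaling of the arrays, robust variance moderation, a fold threshold, other summaries of a gene's probes, the opposite sign and the use of each array alone. A group of 2 samples is too small for a test of outlying samples or of other splits, and these were not run. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for joining, descriptive tests and plots.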

Results

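The expression profile of uncultured rat heart was compared with that of mix1, a pool of cultured bone marrow cells and cultured ear fibroblasts, on 2 arrays that each carried 1 heart sample against the same pool. The comparison asked how gene expression in the heart sample differs from that of these adult cell cultures. Tissue of origin and culture changed together between the channels and could not be separated. All values are log2 ratios of heart over mix1 in the likely direction given with the processing, as mean ± SD over n = 2 arrays.

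The 2 heart samples were compared with each other through their ratios, which share the mix1 pool; this alone raises their correlation, by an amount not estimated here. Across 40012 probes the ratios had a Pearson r of 0.970 and a Spearman rho of 0.943, and across 15613 genes a Pearson r of 0.978; genes and probes are not independent replicates. The difference between the arrays had an SD of 0.34 over genes, and 337 genes (2.16%) differed by at least 2-fold. The gene that differed most was Plppr4, at 0.87 on array 1 and -5.61 on array 2, and Or2y15 (0.43 and -4.43) and Tgm5 (0.54 and -3.94) were also lower on array 2. Among those higher on array 2 were genes of lung surfactant, the protein and lipid film of the air spaces. Surfactant protein genes Sftpa1 and Sftpc had ratios of 0.56 and 0.84 on heart array 1 against 6.51 and 6.68 on heart array 2. Sftpb was at -0.21 and 4.46, and Sftpd at 0.33 and 3.85. Scgb3a2, an airway secretoglobin, was at -0.33 and 3.63, and the epithelial adhesion gene Epcam at -1.02 and 2.69. The surfactant genes did not pass the test over both arrays (limma, adjusted p from 0.215 for Sftpc to 0.333 for Sftpb), and the genes given as differing between the arrays were chosen after their values were seen.

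**Figure D1:**
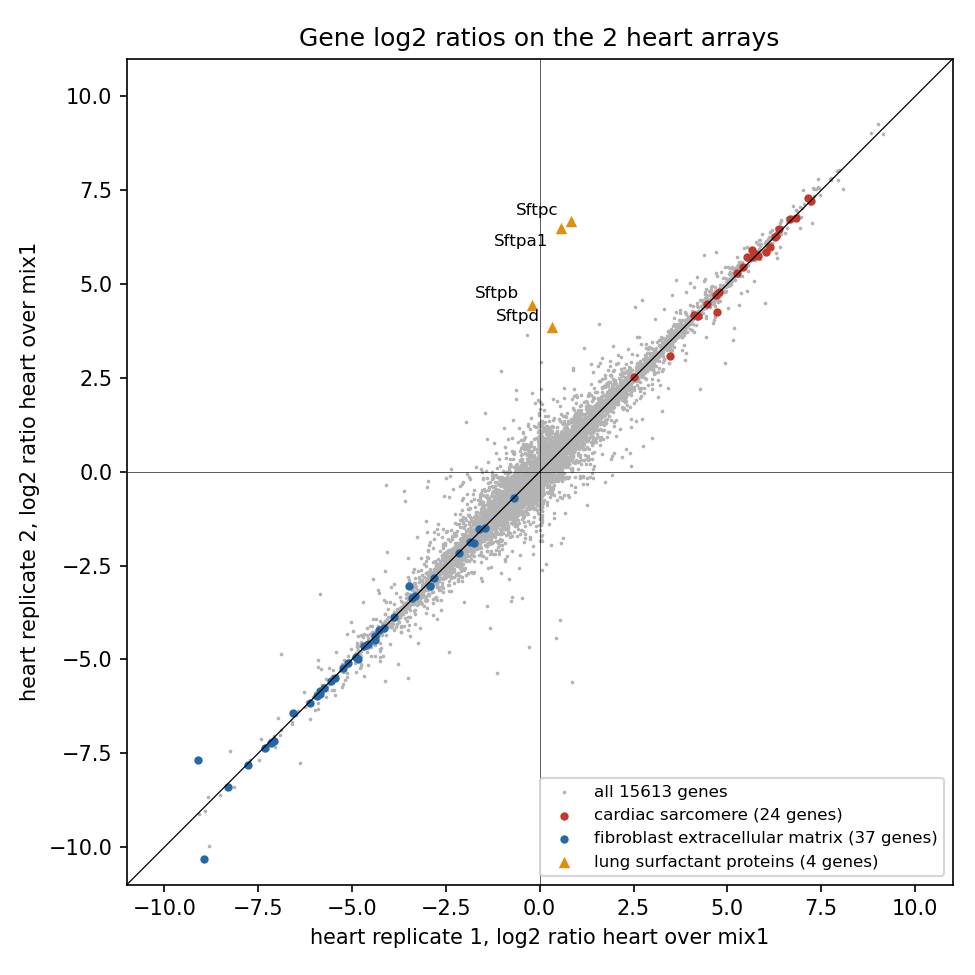
Log2 ratio of heart over mix1 for each of 15613 genes on heart array 1 (horizontal axis) and heart array 2 (vertical axis); the diagonal marks equal ratios. The 24 cardiac sarcomere genes and 37 fibroblast matrix genes lie along the diagonal, while the 4 surfactant protein genes lie near 0 on array 1 and between 3.85 and 6.68 on array 2.

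Heart and mix1 differed in most of the genes measured. In limma's moderated test, 11385 of 15613 genes (72.9%) passed an adjusted p of 0.05, 4905 higher and 6480 lower in heart. Of these, 5683 also differed by at least 2-fold, 2646 higher and 3037 lower, and 363 were at least 16-fold higher and 242 at least 16-fold lower. At the level of probes, 26056 of 40012 passed, 12591 higher and 13465 lower, and 13755 of them differed by at least 2-fold, 7269 higher and 6486 lower. After the arrays were centred, 12895 probes were higher and 12194 lower, so the larger side among probes depends on the setting. As deposited, the median difference between the arrays was -0.01 over probes and -0.004 over genes, although the array medians were 0.01 and -0.14. Centring therefore brought in a shift between arrays that already lay close together. The centred fit of genes also had infinite prior degrees of freedom and ignored each gene's own spread. Calls and lists lost or gained after centring thus decide little. The test as deposited had 1 residual degree of freedom, and the spread of mix1 did not enter it. Of the called genes, 5702 were under 2-fold, down to an absolute log2 ratio of 0.15. Without a dye swap, small calls of this kind cannot be told apart from dye bias.

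Among characterised genes past the test, the 10 largest mean ratios toward heart lay between 7.60 and 9.15. The highest values of single probes, 10.42 on array 1 and 10.16 on array 2, lay above these gene means. Of these 10 genes, Nppb, the B-type natriuretic peptide precursor, had the highest mean at 9.15 ± 0.18, a 567-fold difference. It was followed by the muscle actin-binding gene Xirp2 at 9.07 ± 0.11 and Asb11 at 8.92 ± 0.13. Tesc, a calcium-binding protein, was at 8.01 ± 0.05, and Tmod1, which caps the thin filament, at 7.97 ± 0.06. Tmem182 (7.86), Tpd52l1 (7.80), Asb12 (7.77), Spink8 (7.76) and Mmrn1, a platelet and endothelial multimerin (7.60), completed the 10 largest means. Toward mix1, under the same choice of genes, the matrix metalloproteinase gene Mmp3 had the lowest mean at -9.63 ± 0.98. It was followed by the fast skeletal myosin heavy chain gene Myh1 at -9.40 ± 0.81 and the bone morphogenetic protein antagonist Grem1 at -9.09 ± 0.03. Steap1 (-8.98), the osteopontin gene Spp1 (-8.74), the matricellular gene Ccn4 (-8.56), Col12a1 (-8.39), fibronectin Fn1 (-8.36), macrophage elastase Mmp12 (-8.26) and Cd55 (-7.85), a brake on complement, made up the rest. The order within each set of 10 was not the same on each array or probe. Xirp2 (9.14) lay above Nppb (9.02) on array 1. Mmp3 was at -8.94 on array 1 and -10.32 on array 2, Col12a1 at -9.11 and -7.68, and the Grem1 probe with the smallest difference between arrays at -11.07. The limma adjusted p of these 20 genes lay between 0.0012 and 0.00476, and each had the same sign on both arrays.

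Of the 32 gene lists, 18 differed from the other genes in limma's camera test at a preset correlation, 12 toward heart and 6 toward mix1. With an estimated correlation, 0 of 32 lists passed at either an adjusted or an unadjusted p of 0.05. The adjusted p of the 18 lists lay between 0.392 and 0.6. That form of camera takes its p-value from 1 residual degree of freedom, so hardly any list could pass. The oxidative phosphorylation and tricarboxylic acid cycle list had an estimated correlation of 0.0067, below the preset 0.01. Its unadjusted camera p still went from 1.11e-16 to 0.0729. Other lists of the 18 had estimates above the preset, among them ribosomal proteins (0.2134), calcium handling (0.1429), endothelial (0.1158) and fatty acid oxidation (0.1138). Estimates of others lay below 0, such as creatine and energy buffering (-0.1111). Where the estimate lay above the preset, correlation between genes may also have raised the p-value. The p-values with an estimated correlation therefore do not tell whether correlation between genes removes the list results. After the arrays were centred, the ribosomal protein list no longer passed, and 5 others did: smooth muscle (adjusted p 0.000607), chondrocyte (0.000461), glycolysis (0.0309), bone marrow stromal cell (0.0475) and keratinocyte (0.0475). Adjusted over the list alone, the counts of members past the gene test matched those over all genes in every list but 4. Those were glycolysis (8 lower in place of 7), bone marrow stromal cell (10 lower in place of 9), lymphocyte (2 lower in place of 1) and cholesterol synthesis (15 lower in place of 14).

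**Figure D2:**
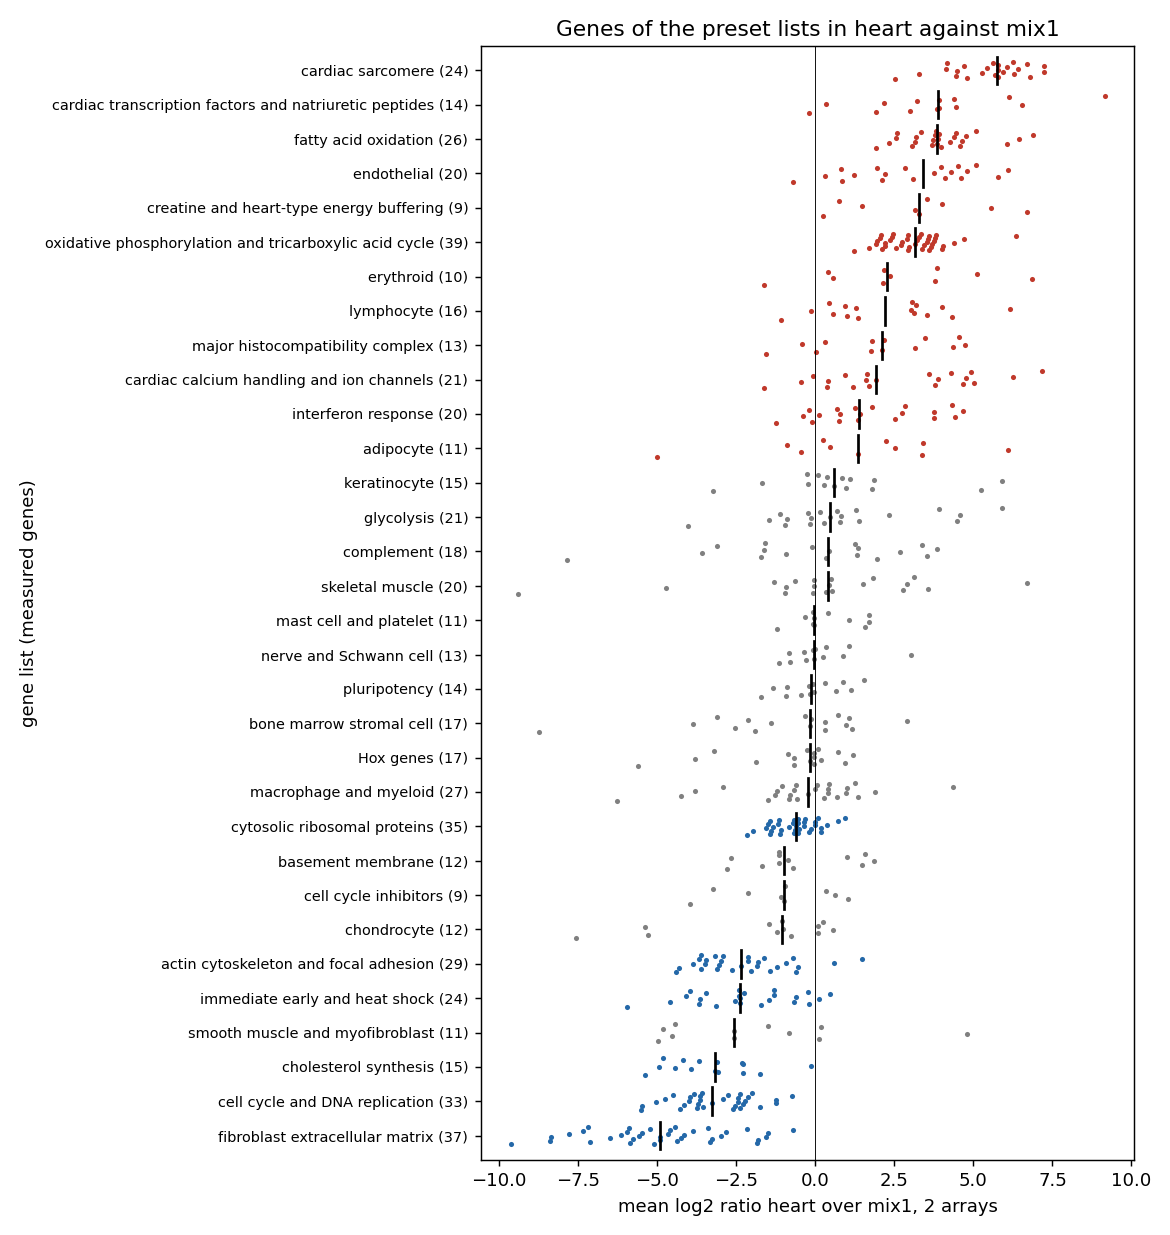
Mean log2 ratio of heart over mix1 (horizontal axis) of each measured gene in the 32 lists (vertical axis, number of measured genes in parentheses), with the list median as a black bar. Red and blue lists passed camera at a preset correlation toward heart (12 lists) and toward mix1 (6 lists), and grey lists did not pass.

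Genes of the cardiac muscle cell were higher in heart. All 24 measured cardiac sarcomere genes passed in that direction, the orientation check, with a median of 5.73 and Mybpc3 and Tnnc1 both at 7.23 (camera adjusted p 9.67e-12, and adjusted p = 0.392 with an estimated correlation). Of 14 cardiac transcription factors and natriuretic peptides, 13 were higher and 1 lower, with a median of 3.88 (camera adjusted p 1.42e-05, and adjusted p = 0.392 with an estimated correlation). Ankrd1, a cardiac stress-responsive ankyrin repeat gene, was at 6.55 ± 0.06, while Hand1 was slightly lower at -0.20 ± 0.01, a call that was lost when the arrays were centred on their medians. Of 21 genes for calcium handling and ion channels, 17 were higher and 2 lower, with a median of 1.92 (camera adjusted p 1.96e-05, and adjusted p = 0.48 with an estimated correlation). Pln, which encodes the calcium pump regulator phospholamban, was at 7.18 ± 0.08 and the potassium channel gene Kcnj5 at 6.26 ± 0.002. Asph was lower at -1.63 ± 0.02 (-2.41 for its probe with the smallest difference between arrays), and Gja1, the gap junction connexin gene of the working myocardium, at -0.46 ± 0.01, a call likewise lost after centring. Hcn2 did not pass unless the arrays were centred (0.39 ± 0.25).

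Skeletal muscle genes were divided, and most smooth muscle genes were lower in heart. Of 20 skeletal muscle genes, 10 were higher, 4 lower and 6 did not pass, and the list did not pass (median 0.39, camera adjusted p 0.0987). Ckm, the muscle creatine kinase gene that heart also expresses, was at 6.71 ± 0.01 and Tnnt1 at 3.57 ± 0.72. Besides Myh1, the myosin gene Myh2 was lower in heart at -4.73 ± 0.57, while Actn3 did not pass unless the arrays were centred (-0.92 ± 0.49). Of 11 smooth muscle and myofibroblast genes, 8 were lower and 1 higher, with a median of -2.56 that did not pass as a list unless the arrays were centred (camera adjusted p 0.103 as deposited). Tagln was at -4.96 ± 0.02 and Tpm2 at -4.82 ± 0.02. The higher gene was desmin (Des, 4.79), the intermediate filament of muscle, which also stands in the sarcomere list.

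Genes of oxidative metabolism were higher in heart. All 26 genes of fatty acid oxidation passed in that direction with a median of 3.86 (camera adjusted p 5.94e-12, and adjusted p = 0.392 with an estimated correlation). Pdk4, a kinase that restrains pyruvate oxidation, was at 6.87 ± 0.12 (5.11 for its probe with the smallest difference between arrays) and the fatty acid transporter gene Cd36 at 6.44 ± 0.04. All 39 genes of oxidative phosphorylation and the tricarboxylic acid cycle were higher, with a median of 3.17 (camera adjusted p 3.55e-15, and adjusted p = 0.392 with an estimated correlation). The muscle forms of cytochrome oxidase subunits, Cox8b at 6.33 ± 0.03 and Cox6a2 at 4.69 ± 0.03, had the largest ratios. All 9 genes of creatine and heart-type energy buffering were higher, with a median of 3.30 and Ckmt2, the mitochondrial creatine kinase, at 5.57 ± 0.09 (camera adjusted p 9.72e-05, and adjusted p = 0.392 with an estimated correlation). Glycolysis genes went both ways, with 13 of 21 higher and 7 lower (median 0.45, camera adjusted p 0.0774). Ldhb (5.91 ± 0.03) and the muscle mutase gene Pgam2 (4.57 ± 0.05) were higher in heart, and the lactate exporter gene Slc16a3 (-4.03 ± 0.05) and Aldoc (-1.48 ± 0.04) were lower.

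Genes of the fibroblast extracellular matrix were lower in heart. All 37 measured members passed in that direction, with a median of -4.91 (camera adjusted p 3.43e-11, and adjusted p = 0.392 with an estimated correlation). Mmp3, Col12a1 and Fn1 were among them. Of 29 genes of the actin cytoskeleton and focal adhesions, 27 were lower and 2 higher, with a median of -2.34 (camera adjusted p 5.63e-06, and adjusted p = 0.392 with an estimated correlation). Actn1 was at -4.39 ± 0.06 and S100a6 at -4.32 ± 0.01, and the 2 higher genes were Actn4 (1.47 ± 0.04) and Pxn (0.60 ± 0.05). Basement membrane genes did not pass as a list (camera adjusted p 0.428), with 8 of 12 lower, among them Nid2 at -2.81 and Col4a2 at -2.66. The laminin chains Lama5 (1.86) and Lama2 (1.56) were among the 4 higher in heart. Of 17 bone marrow stromal genes, 6 were higher and 9 lower (median -0.16, camera adjusted p 0.707). Spp1 and the surface glycoprotein gene Thy1 (-3.86 ± 0.50) were lower in heart, and Alpl (2.91 ± 0.03) and Vcam1 (1.06) were higher.

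Genes of proliferation, sterol synthesis and the immediate early response were lower in heart than in the cultured cells. All 33 cell cycle and DNA replication genes were lower, with a median of -3.27 (camera adjusted p 6.86e-09, and adjusted p = 0.392 with an estimated correlation). The mitotic kinase gene Cdk1 was at -5.52 ± 0.01 and Kif20a at -5.48 ± 0.03. Of 9 cell cycle inhibitors, 6 were also lower, including Cdkn2b (-3.97 ± 0.22) and Cdkn2a (-3.22 ± 0.30), while Rbl2 (1.03) and Rb1 (0.63) were higher (camera adjusted p 0.421). Of 15 cholesterol synthesis genes, 14 were lower and 0 higher, with a median of -3.18, and Sqle, the squalene epoxidase gene, was at -5.40 ± 0.17 (camera adjusted p 1.61e-05, and adjusted p = 0.392 with an estimated correlation). Fdft1 did not pass over all genes (-0.15, adjusted p 0.0502). Of 24 immediate early and heat shock genes, 22 were lower, with Fos at -5.94 ± 0.07 and Egr1 at -4.61 ± 0.05, and Ddit3 was higher at 0.48 (camera adjusted p 2.86e-05, and adjusted p = 0.392 with an estimated correlation). Of 35 ribosomal protein genes, 26 were lower and 4 higher, with a median of -0.61. That list passed camera (adjusted p 0.00389), but not after the arrays were centred (0.0909), and its adjusted p = 0.6 with an estimated correlation.

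Genes of vessels, red blood cells, lymphocytes and the interferon response were for the most part higher in heart, while those of myeloid cells went both ways. Of 20 endothelial genes, 19 were higher, with a median of 3.42 (camera adjusted p 1.88e-07, and adjusted p = 0.392 with an estimated correlation). Fabp4, a lipid-binding protein of capillaries and fat cells, was at 6.09 ± 0.01 and the vascular growth factor receptor gene Kdr at 5.79 ± 0.02, while the water channel gene Aqp1 was lower at -0.72 ± 0.04. Of 10 erythroid genes, 9 were higher, with Hbb-b1 at 6.86 and Hbb at 5.11, although near-identical globin copies can share a probe (camera adjusted p 0.000828, and adjusted p = 0.392 with an estimated correlation). The lower one was the transferrin receptor gene Tfrc (-1.61), which dividing cells also express. Of 16 lymphocyte genes, 13 were higher and 1 lower, with Cd3g at 6.15 ± 0.07 and Cd2 at 4.34 ± 0.43 (camera adjusted p 0.0002, and adjusted p = 0.392 with an estimated correlation). Cd3e did not pass as deposited, at 2.44 on array 1 and 0.16 on array 2. It passed only in the centred fit, which ignores each gene's own spread. Of 27 macrophage and myeloid genes, 10 were higher and 13 lower (median -0.22, camera adjusted p 0.932). Cd74 (4.35) and Cd163 (1.88) were higher, and the chemokine genes Ccl2 (-6.27) and Ccl3 (-4.26) were lower. Of 13 genes of the major histocompatibility complex, 10 were higher and 2 lower, with the class II genes RT1-Bb at 4.75 ± 0.08 and RT1-Da at 4.56 ± 0.02 (camera adjusted p 0.00169, and adjusted p = 0.392 with an estimated correlation). The lower genes were RT1-DMa, also of class II, at -1.55 ± 0.02 and Tap2 at -0.43. Cd74 stands in this list as well as in the myeloid list. Of 20 interferon response genes, 15 were higher and 3 lower, with Mx2 at 4.67 ± 0.10 and Oas1a at 4.43 (camera adjusted p 0.000404, and adjusted p = 0.392 with an estimated correlation).

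Markers of the remaining cell types were mixed. Of 11 adipocyte genes, 7 were higher and 3 lower, with the adiponectin gene Adipoq at 3.42 ± 0.11 and the desaturase gene Scd at -5.01 ± 0.14 (camera adjusted p 0.0476, and adjusted p = 0.487 with an estimated correlation). The highest ratio in that list was that of Fabp4 (6.09), which also stands in the endothelial list. Of 12 chondrocyte genes, 7 were lower and 2 higher, with Col11a1 at -7.58 ± 0.14 and the cartilage proteoglycan gene Acan at -5.37 ± 0.27 (camera adjusted p 0.158). Of 15 keratinocyte genes, 7 were higher and 3 lower (camera adjusted p 0.0774). The largest ratios in that list were those of Dsp (5.89 ± 0.08), a desmosome gene that heart muscle also expresses, and Krt19 (5.26 ± 0.25), while Tp63 was at -3.23 ± 0.29. With the probe of smallest difference between arrays, Dsp was at 4.32 and Tp63 at -1.37. The keratinocyte list's median was 0.05 on array 1 and 0.67 on array 2, the array with the surfactant transcripts, and Cdh1 was at 0.02 and 2.20. Cdh1 did not pass as deposited and passed only in the centred fit, which ignores its spread.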

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

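The alternatives without the cluster of probes near 0, with natural logs and with symbols not updated were chosen after seeing the data. Counts of called genes lay between 10278 with the arrays centred on their medians and 11599 with the probe of smallest difference between arrays, beside 11385 as reported. Choosing that probe selects for the small spread that the test then uses, so calls gained there may follow from the choice. A further requirement of at least 2-fold left 13755 probes and 5683 genes. Of the 10278 genes called after centring, which moved array 2 by 0.14, 9613 were shared with the 11385; that fit pooled the spread over all genes, so its p-values ignore the spread of each gene. Centring ended the calls of Gja1, Hand1, Chad, Ifit2 and Tap2, and Hcn2, Actn3, Kitlg, Cd3e, Hapln1, Cdh1, Sox2 and Hoxc4, not called as deposited, passed there. Scaling gained Hapln1 and Hoxc4, and the probe of smallest difference gained Pfkl, Kitlg, Kit and Fdft1. Of the 32 lists, 0 passed camera with an estimated correlation, where 1 degree of freedom left little power, and 22 passed after centring. All 32 passed fry, which sets a list's genes against 0 and not against other genes. Divided lists passed it too, such as complement (10 higher and 7 lower). The medians of 26 lists, 16 higher and 10 lower, lay outside the middle 95% of random lists, including 8 that did not pass camera: skeletal muscle, smooth muscle, glycolysis, basement membrane, chondrocyte, keratinocyte, cell cycle inhibitors and complement. Pearson r between the arrays was 0.978 over genes, 0.984 over probes of at least 2-fold and 0.772 over probes under 2-fold, sets selected on the mean of the same arrays. With the probe of smallest difference, the sign turned for Mbp (0.42), Ifit2 (0.23) and Serping1 (0.46), and for Smtn (-0.04), which passed neither way; Grem1, Asph, Pdk4, Ms4a2, Dsp and Tp63 moved by over 1.5 times in fold. The cause was not tested. Counts at 2-fold or more with 1 array left out, which has no test, were 14275 to 14636 for probes (14227 over both) and 5825 to 5902 for genes (5806 over both). Read as natural logs, 19019 probes and 7745 genes reached 2-fold. Turning the sign of all values exchanges higher and lower. Base 10 was not run because the values contradict it, and leaving out values of exactly 0 removed nothing. No paired analysis was possible because there was 1 group. Signal over background was not used here, so the ratios of dim probes could not be bounded.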

Other observations

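Developmental and nerve genes were divided between heart and mix1. Of 17 Hox genes, which pattern the body axis, 8 were lower in heart, 2 higher and 7 did not pass (camera adjusted p 0.334). Hoxa2 was at -5.61 ± 0.11 and Hoxc10 at -3.80 ± 0.06, while Hoxd3 was at 1.19 ± 0.09 and Hoxc8 at 0.93 ± 0.06. Of 14 pluripotency genes, 4 were higher and 5 lower (camera adjusted p 0.932), with the DNA methyltransferase gene Dnmt3b at 1.54 ± 0.02 and Klf4 at -0.92 ± 0.03. Sox2 did not pass as deposited, at -1.71 ± 1.82, and passed only in the centred fit, which ignores its spread. Of 13 nerve and Schwann cell genes, 4 were higher and 4 lower (camera adjusted p 0.756), with the neuronal filament gene Prph at 3.04 ± 0.02, Sox10 at 1.07 and the myelin gene Pmp22 at -1.16. The median of that list was below 0 (-0.05) while its mean was above 0 (0.15), as was the direction of its test.

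Complement and mast cell genes were divided as well. Of 18 complement genes, 10 were higher and 7 lower in heart (camera adjusted p 0.333). Clu was at 3.86 ± 0.02 and the terminal component gene C6 at 3.53 ± 0.03, while C3, the central component, was at -3.57 ± 0.10. The complement median was above 0 (0.40), as was the direction of its test, and the mean was below 0 (-0.02). Of 11 mast cell and platelet genes, 5 were higher, 1 lower and 5 did not pass (camera adjusted p 0.351), with the mast cell receptor gene Ms4a2 at 1.70 ± 0.55 (2.80 for its probe with the smallest difference between arrays) and the histamine synthesis gene Hdc at 1.69 ± 0.05. The median of that list was below 0 (-0.03), and its mean (0.43) and the direction of its test were above 0.

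The tests of faulty spots, of another tissue, of the cluster near 0 and of the myosin genes were chosen after the result was seen, and the test of other lung genes was written before its result was seen. The 4 surfactant protein genes were higher on heart array 2 than on array 1, and were the largest gene family among the 15 characterised probes more than 3 higher there on the log2 scale, a bound set after the values were seen. Only 0.65% of 10000 random draws of 15 probes held at least 4 genes of any family (shared first 4 letters of the symbol). The surfactant family had itself prompted this test, so the share argues only weakly against isolated faulty spots. Sarcomere genes had a median difference between the arrays of 0.01 (0.0076, SD over genes 0.157), which argues against a second sample of a tissue other than heart. A candidate explanation is lung RNA in heart sample 2: 30 other lung epithelial genes had a median difference of 0.18, at percentile 100 of 10000 random lists, the highest of which reached 0.11. Of the 30, 18 were higher and 12 lower on array 2, 7 and 2 of them by more than 0.5. Foxa2 (-0.16 and 1.22), Cldn18 (0.01 and 1.27) and Esrp1 (-0.48 and 0.67) rose most. The alveolar genes Napsa (3.22 and 3.59) and Slc34a2 (1.91 and 1.62) differed little between arrays, and Nkx2-1 (0.37 and 0.18) and Lpcat1 (-1.49 and -1.77) were slightly lower on array 2. The evidence therefore rests on a small shift of the list. The random lists were drawn from all genes and not matched on signal, so the percentile may be too extreme if many lung genes lay near background. No biological explanation was tested, since both samples belong to 1 group.

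A narrow cluster of 3891 probes (9.73%) lay near 0, at a median of 0.03 on array 1 and -0.15 on array 2. The bounds were drawn from the data and put every member below 0 on array 2, so that the share with the same sign on both arrays (20.9%) was limited by construction and decides nothing; small real differences between heart and mix1 stay open. Probes without signal in either channel are a candidate explanation, since olfactory and vomeronasal receptor genes, seldom transcribed outside sensory tissue, made up 18.9% of named probes inside and 4.65% outside (odds ratio 4.77, 95% interval 4.05 to 5.60). Without the cluster, 11492 of 14698 genes were called.

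The fast myosin genes Myh1 (-9.40) and Myh2 (-4.73) were far lower in heart than in mix1. Among the other genes of the skeletal muscle list, Myh8 (-1.30) and Myf5 (-0.97) were also lower, named after their values were seen. The 18 others had a median of 0.47 with an SD over genes of 2.05, and heart itself expresses several of them. Among fast skeletal muscle genes other than myosins, Actn3 (-0.92), Atp2a1 (-0.64) and Pvalb (-0.05) were lower but did not pass. Myl11, Tnnt3, Tnni2, Ryr1, Casq1 and Ckm passed toward heart, between 0.34 and 6.71. Since heart itself expresses several genes of the list, a ratio toward heart does not exclude fast skeletal muscle cells in the cultures. Actn3 (-1.27 and -0.57) and Atp2a1 (-1.02 and -0.27) leaned toward mix1 on both arrays, so the source of Myh1 stays undecided. Myh8 and Myf5 were also lower in heart, and skeletal muscle cells of any kind were neither shown nor excluded. Whether the probes read another transcript could not be told apart from a real difference, since Myh1 and Myh2 have 2 probes together, 1 each. A difference between heart and the cultured cells stays open and untested.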
